A study of Mus musculus with 9 samples.

How the data were processed

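RNA was measured in left ventricular tissue of 9 male C57BL/6 mice aged 8 weeks, from the infarct region in mice with ischemia-reperfusion (I/R). Per the labels' protocols, I/R was a ligation of the left anterior descending coronary artery for 1 hour, followed by reflow. The groups were sham-operated mice (1, 2 and 3), mice at 1 day after I/R (4, 5 and 6) and mice at 14 days after I/R (3 mice). The time after surgery at which sham tissue was collected is not given in the labels. The 3 count columns of the 14-day group share 1 name, so these libraries are called A, B and C, as names only. The groups share no replicate numbers and no pairing was made.

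Per the labels' protocols, RNA was extracted with TRIzol and made into stranded libraries from total RNA after depletion of ribosomal RNA. Per the submitters' processing notes, STAR 2.7.1a and the mouse build GRCm38 (mm10) were used. The deposited values are whole-number counts per gene, not normalized. The counting program, annotation release, strand setting and treatment of reads with several matches are not given in the sources used here. Genes that share exonic bases with another gene, or that have near-identical copies (the hemoglobin, H2 and Ccl21a genes), are therefore uncertain. Of the 153 named genes, 52 shared exonic bases with another annotated gene and 24 shared at least 10% of theirs with 1 or more genes, namely Spp1, Jund, Nr2f6, Endog, Nppa, Pln, Mt2, Tagln, Folr2, Fbn1, Sfrp2, Csf1r, Ccnd1, Cxcl16, Smtn, Cox5a, Sox17, Tapbp, Alas2, Bhlhe41, Tbx18, H2-Q4, H2-DMa and Higd1a.

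The table held 38293 genes, of which 36429 were in GENCODE release M21 of GRCm38, used for names, positions and GC content (of the longest transcript). Total counts per library ran from 20215781 to 36816818, and from 7.22M to 15.97M without ribosomal RNA genes. These depths set the precision of low genes, and intervals given for ratios of low counts cover counting error only. Replicates of 1 group differed by more than sampling noise in every pair (chi-square per degree of freedom from 6.90 to 89.7), so each library was 1 replicate.

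Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, edgeR's filter on low counts, robust dispersion and all 9 libraries in 1 fit, in which the groups share 1 estimate of the spread. The filter kept 14124 genes. Adjusted p is the Benjamini-Hochberg value, with a threshold of 0.05. CPM is a gene's count per 1M counts of the TMM-scaled library, and log2 folds and SE come from the fit. Of 46 gene lists, 42 had at least 3 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera was repeated with the correlation estimated for each list, and fry was run beside it, which tests whether a list's genes move on balance one way. Unlike camera, fry does not set a list against the other genes. A fry call therefore does not show that a list moved more than the other genes. Shares of counts were compared with two-sided exact permutation tests, for which 3 against 3 libraries give no p below 0.1.

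The groups, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison and direction, the 6 called genes with the largest log2 fold among those with at least 10 CPM in the higher group, groups that do not overlap and a symbol that is not that of a predicted or numbered clone gene. For 15 lists it took the 2 called members with the highest mean CPM in the direction with more calls and 1 in the other. For the other lists it took the called members where these were 5 or fewer. Some genes that the rule took are not reported here. Alternatives were the size factors and Wald test of DESeq2 1.42.0, total count only (no scaling factors), upper-quartile scaling, scaling without mitochondrially encoded genes, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit of the groups compared alone, a test against a 2-fold change and each mouse left out in turn. An offset for GC content and length, and the attention to the fit without mouse 6, were chosen after the data were seen. On simulated counts for 1 day against sham (13680 genes) the test recovered 13.4% of genes changed by a log2 fold of 0.5, 80.0% at 1 and 95.2% at 2, with 9 false calls among 137. The simulated libraries followed the sham mean with most genes unchanged, while the real comparison called 7649 of 14124 genes. These rates may therefore not carry over. Figures were drawn with matplotlib 3.10.9.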

Results

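Total RNA of the left ventricle (the infarct region after I/R) was sequenced in 3 sham mice, 3 mice at 1 day and 3 mice at 14 days after I/R. The comparisons ask which transcripts differ from sham early and late after the injury, and between both times. Total counts were 25218174, 32501962 and 20215781 for sham mice 1, 2 and 3, then 30209130, 21950845 and 20861848 for mice 4, 5 and 6, and 33475852, 36816818 and 23621297 for the 14-day libraries A, B and C. Mitochondrially encoded genes, ribosomal RNAs included, took 67.7% ± 3.60 of the counts in sham, 59.1% ± 6.19 at 1 day and 67.4% ± 2.10 at 14 days (SD, n = 3 per group). Against sham the two-sided exact permutation p was 0.1 at 1 day, the smallest that 3 against 3 can give, and 1 at 14 days. Without ribosomal RNA genes the shares were 18.9% ± 2.01, 12.4% ± 2.95 and 15.5% ± 1.67 (SD, n = 3, exact permutation p = 0.1 for each time against sham).

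The first principal component of log2 CPM held 64.4% of the variance and the second 19.4%. On the first, mice 4 and 5 lay at 78.0 and 78.7, mouse 6 at 37.2 and the other libraries between -40.9 and -16.9. On the second, sham lay between 23.5 and 29.8 and the 14-day libraries between -49.1 and -13.1. Among the 3 groups, 8897 of 14124 genes differed (edgeR quasi-likelihood test, adjusted p under 0.05).

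**Figure D1:**
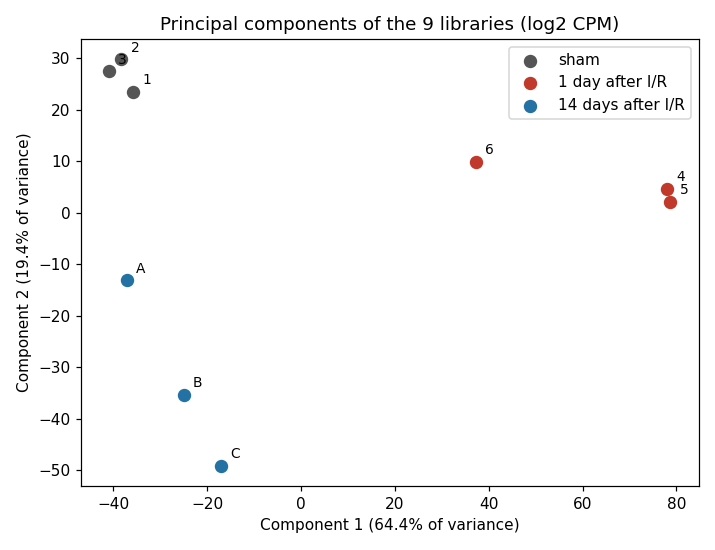
Each point is 1 library on the first 2 principal components of log2 CPM (64.4% and 19.4% of the variance), coloured by group. Mouse 6 sits at 37.2 on the first component, between mice 4 and 5 (78.0 and 78.7) and the sham libraries.

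At 1 day after I/R, genes of recruited leukocytes, tissue stress and matrix were higher than in sham, and genes of energy metabolism were lower. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) of GRCm38, which encodes the secreted matrix protein osteopontin, had 0.0829 ± 0.0186 CPM in sham and 98.0 ± 11.7 CPM at 1 day (SD, n = 3 per group, log2 fold 10.07, SE 0.43, edgeR adjusted p = 1.85e-06). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), a lipocalin of neutrophil granules, had 0.490 ± 0.0631 CPM in sham and 56.2 ± 22.5 CPM at 1 day (SD, n = 3 per group, log2 fold 6.83, SE 0.39, edgeR adjusted p = 6.20e-06). Ucp3 (ENSMUSG00000032942, chromosome 7, 100472990 to 100486432), a mitochondrial inner membrane carrier, had 20.2 ± 6.89 CPM in sham and 2.30 ± 2.04 CPM at 1 day (SD, n = 3 per group, log2 fold -3.23, SE 0.52, edgeR adjusted p = 9.51e-04). In all, 4153 genes rose and 3496 fell, 7649 of 14124, and 810 passed a test against a 2-fold change.

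Among called genes with at least 10 CPM in the higher group and groups that did not overlap, predicted, clone and unnamed genes left out, the other largest rises (log2 fold, SE) were in Chil3 (6.11, SE 0.25), Slfn4 (5.90, SE 0.33) and the protease inhibitor gene Timp1 (5.83, SE 0.41). Ankrd2, which encodes a muscle ankyrin repeat protein, had 2105 counts over the 1-day libraries and 3 over the sham libraries, a ratio of 529.6 with a 95% counting interval of 181 to 2570.3. The largest falls among such genes, with Ucp3, were in Lrtm1 (-3.51, SE 0.54), Armc2 (-3.03, SE 0.49), the sodium channel subunit Scn4b (-2.90, SE 0.50), the potassium channel partner Kcnip2 (-2.77, SE 0.43) and the ephrin Efnb3 (-2.75, SE 0.46). Exons of Spp1 overlap those of another gene, so its counts are uncertain.

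Leukocyte genes rose. Of 14 neutrophil genes 12 rose and 1 fell (median log2 fold 4.30, camera adjusted p = 2.59e-05, adjusted p = 0.659 with an estimated correlation). The receptor gene Csf3r (4.18, SE 0.48) and Lcn2 were the most abundant that rose, and G0s2 (-0.94, SE 0.17) fell. Of 12 monocyte and early recruited macrophage genes 12 rose (median log2 fold 3.59, camera adjusted p = 4.42e-07, adjusted p = 0.627 with an estimated correlation). Vcan (1.71, SE 0.31) and Thbs1 (2.42, SE 0.32) were the most abundant called members, and both are also in the matrix glycoprotein list. Of 18 general macrophage genes 10 rose (median log2 fold 0.97, camera adjusted p = 7.51e-04, adjusted p = 0.710 with an estimated correlation). Lyz2 (0.86, SE 0.20) and Ctss (1.54, SE 0.26) were the most abundant called members, and 17 rose with total count only (median 1.46). Of 23 cytokine and chemokine genes 19 rose and 1 fell (median log2 fold 2.46, camera adjusted p = 5.82e-07, adjusted p = 0.633 with an estimated correlation). Csf1 (0.91, SE 0.11) and Ccl6 (2.41, SE 0.17) were higher and Cxcl14 (-0.77, SE 0.20) was lower. Of 5 red blood cell genes 5 fell (median log2 fold -1.26, camera adjusted p = 0.00556, adjusted p = 0.659 with an estimated correlation), with Alas2 (-1.0, SE 0.23), Hbb-bs (-1.09, SE 0.20), Hba-a2 (-1.26, SE 0.20), Hba-a1 (-1.29, SE 0.24) and Hbb-bt (-1.47, SE 0.21) lower, and 4 fell with total count only (median -0.76).

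Stress and growth genes rose. Of 15 cardiac stress genes 15 rose (median log2 fold 2.57, camera adjusted p = 1.25e-09, adjusted p = 0.627 with an estimated correlation). The actin-binding proteins Xirp2 (3.10, SE 0.23) and Flnc (3.56, SE 0.26) were the most abundant called members. Of 18 heat shock and unfolded protein response genes 13 rose (13 rose and 1 fell adjusted over the list alone, median log2 fold 1.19, camera adjusted p = 4.52e-05, adjusted p = 0.659 with an estimated correlation). Of 12 NRF2 target and metallothionein genes 10 rose and 1 fell (median log2 fold 1.29, camera adjusted p = 7.51e-04, adjusted p = 0.627 with an estimated correlation). Of 32 cytosolic ribosomal protein genes 31 rose (median log2 fold 0.61, camera adjusted p = 1.77e-08, adjusted p = 0.659 with an estimated correlation), a median of 1.10 with total count only. Of 28 cell cycle genes 24 rose (25 rose adjusted over the list alone, median log2 fold 1.59, camera adjusted p = 1.14e-05, adjusted p = 0.708 with an estimated correlation). The cyclin Ccnd1 (0.36, SE 0.11) and the proliferation marker Mki67 (1.49, SE 0.41) were the most abundant called members. The median log2 CPM of the cell cycle list above the sham mean was 1.70 in mouse 4, 2.04 in mouse 5 and 0.40 in mouse 6.

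Matrix genes rose while resting fibroblast genes fell. Of 19 collagen genes 11 rose (median log2 fold 0.86, camera adjusted p = 0.0126, adjusted p = 0.767 with an estimated correlation). The basement membrane chains Col4a1 (1.20, SE 0.17) and Col4a2 (1.19, SE 0.16) were the most abundant called members. Of 30 matrix glycoprotein and crosslinking genes 20 rose and 2 fell (median log2 fold 1.01, camera adjusted p = 0.00327, adjusted p = 0.767 with an estimated correlation). Sparc (0.76, SE 0.21) and Fbn1 (1.03, SE 0.25) were higher and Fbln1 (-1.56, SE 0.31) was lower. Of 19 matrix protease and inhibitor genes 11 rose and 2 fell (median log2 fold 0.92, camera adjusted p = 0.0117, adjusted p = 0.708 with an estimated correlation). Of 19 TGF-beta and activin genes 11 rose and 1 fell (median log2 fold 0.60, camera adjusted p = 0.00788, adjusted p = 0.724 with an estimated correlation). Of 14 resting fibroblast genes 10 fell and 2 rose (median log2 fold -1.21, camera adjusted p = 0.00175, adjusted p = 0.659 with an estimated correlation). Gsn (-1.79, SE 0.23) and Dcn (-1.17, SE 0.25) were lower and Col15a1 (0.49, SE 0.16) was higher, a call that ended with the GC and length offset and without sham mouse 2, sham mouse 3, mouse 4 or mouse 5. With total count only 8 fell and 3 rose among resting fibroblast genes (median -0.74), and the medians were 1.35 for collagens, 1.39 for matrix proteases and 1.08 for TGF-beta genes. The activated fibroblast list did not pass: of 14 genes 7 rose and 2 fell (median log2 fold 1.42, camera adjusted p = 0.119). Postn (1.39, SE 0.50) and Col8a1 (1.73, SE 0.26) were higher and the smooth muscle actin gene Acta2 (-0.63, SE 0.15) was lower.

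Energy metabolism and contraction genes fell, beside the lower mitochondrial share given above. Of 50 nuclear-encoded oxidative phosphorylation genes 50 fell (median log2 fold -0.90, camera adjusted p = 1.51e-15, adjusted p = 0.659 with an estimated correlation). The ATP synthase subunits Atp5b (-0.74, SE 0.19) and Atp5a1 (-0.91, SE 0.20) were the most abundant called members. Of 28 genes of fatty acid uptake and oxidation 27 fell (28 fell adjusted over the list alone, median log2 fold -1.22, camera adjusted p = 1.43e-10, adjusted p = 0.659 with an estimated correlation). The lipase Lpl (-1.22, SE 0.27) and the transporter Cd36 (-0.79, SE 0.17) were the most abundant called members. Of 15 tricarboxylic acid cycle genes 15 fell (median log2 fold -0.88, camera adjusted p = 1.70e-06, adjusted p = 0.672 with an estimated correlation). Of 7 mitochondrially encoded messenger RNAs 6 fell (7 fell adjusted over the list alone, median log2 fold -0.73, camera adjusted p = 0.00919, adjusted p = 0.708 with an estimated correlation). Of 20 calcium handling and ion channel genes 13 fell and 1 rose (14 fell and 1 rose adjusted over the list alone, median log2 fold -0.99, camera adjusted p = 6.34e-05, adjusted p = 0.708 with an estimated correlation). The calcium pump Atp2a2 (-1.32, SE 0.31) and its inhibitor Pln (-1.82, SE 0.36) were lower. Of 20 sarcomere genes 13 fell and 1 rose (14 fell and 1 rose adjusted over the list alone, median log2 fold -0.54, camera adjusted p = 9.84e-05, adjusted p = 0.708 with an estimated correlation). Myh6 (-1.41, SE 0.32) and Tpm1 (-0.48, SE 0.18) were lower and Smpx (0.35, SE 0.10) was higher. Under total count only 29 oxidative phosphorylation (median log2 fold -0.44), 24 fatty acid (median -0.77), 6 tricarboxylic acid cycle (median -0.41) and 2 mitochondrially encoded genes (median -0.28) fell. Of calcium handling genes 10 fell and 2 rose there (median -0.53), of sarcomere genes 8 fell and 2 rose (median -0.07), and the log2 fold of Tpm1 turned to 0.01. The GC and length offset left 3 of the mitochondrially encoded genes lower (median -0.46).

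Other lists did not pass as lists. Of 18 blood endothelial genes 7 fell and 1 rose (7 fell adjusted over the list alone, median log2 fold -0.19, camera adjusted p = 0.0641), a median that turned to 0.29 with total count only, where 5 rose and 1 fell. Of these, Fabp4 (-0.46, SE 0.13) and the growth factor receptor gene Kdr (-1.24, SE 0.15) fell, and with total count only the log2 fold of Fabp4 turned to 0.01. The call of Sox17 (0.62, SE 0.24) ended under DESeq2, DESeq2 size factors in edgeR, upper-quartile scaling, the GC and length offset, the fit of both groups alone, and without sham mouse 2, sham mouse 3, mouse 4, mouse 5, library B or library C. Of 18 immediate early genes 10 rose and 3 fell (11 rose and 4 fell adjusted over the list alone, median log2 fold 0.71, camera adjusted p = 0.0677). Of 15 hypoxia response genes 5 fell and 3 rose (median log2 fold -0.34, camera adjusted p = 0.161), a median that turned to 0.15 with total count only. Of 10 tissue-resident macrophage genes 3 fell and 2 rose (median log2 fold -0.35, camera adjusted p = 0.488), with Mrc1 (0.53, SE 0.17) and F13a1 (0.72, SE 0.15) higher and Cd163 (-0.48, SE 0.16), Gas6 (-0.50, SE 0.17) and Folr2 (-0.79, SE 0.16) lower. That median turned to 0.14 with total count only. Of 7 dendritic cell genes 4 rose and 1 fell (median log2 fold 1.12, camera adjusted p = 0.370), with Itgae (1.80, SE 0.56), Cd209a (2.11, SE 0.64), Irf8 (1.12, SE 0.27) and Flt3 (3.22, SE 0.73) higher and Zbtb46 (-0.37, SE 0.11) lower. For the remaining 15 tested lists camera adjusted p was 0.579 or more.

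Called members of those lists with 5 or fewer calls were, for late-scar fibroblasts, Prg4 (4.61, SE 0.26), Thbs4 (2.75, SE 0.51), Clu (1.79, SE 0.18) and Acan (2.91, SE 0.63) higher and Angptl7 lower. They were Pdpn (3.16, SE 0.25) higher and Prox1 (-1.32, SE 0.18) lower for lymphatic endothelium, Aldh1a2 (3.40, SE 0.25) and Krt18 (1.91, SE 0.49) higher and Wt1 (-1.09, SE 0.22) lower for epicardium and Mbp (1.63, SE 0.26) higher and Cdh19 (-0.61, SE 0.20) and Kcna1 (-1.80, SE 0.28) lower for Schwann cells. Single calls in a list were Nppa (3.85, SE 0.35) higher for the atrium, Pf4 (0.85, SE 0.25) higher for platelets, Ighm (-1.18, SE 0.37) lower for B cells, Cd28 (-1.06, SE 0.18) lower for T cells and Tnnt3 (3.62, SE 0.69) higher for fast skeletal muscle, the T cell and fast muscle lists being too short for camera. For MHC class I they were Tap1 (0.46, SE 0.17) higher and Tapbp (-0.26, SE 0.09) and H2-Q4 (-0.43, SE 0.14) lower, and for class II H2-Aa (-0.97, SE 0.29) and H2-Eb1 (-0.91, SE 0.29) lower. Adjusted over the list alone 0 MHC class I genes were called, while 5 had an unadjusted edgeR p under 0.05, and DESeq2 called 3 and limma-voom 3. For the clock they were Per1 (1.16, SE 0.42), Bhlhe41 (1.30, SE 0.11) and Per2 (2.38, SE 0.33) higher and Npas2 (-1.71, SE 0.24) and Arntl (-1.57, SE 0.30) lower, and 2 rose and 2 fell adjusted over the list alone. Angptl7 had 32 counts over the sham libraries and 1 over the 1-day libraries, a ratio of 42.4 with a 95% counting interval of 7.08 to 1726. Cd163, Zbtb46, Tapbp and H2-Q4 turned direction with total count only.

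Of the 42 lists 21 passed, 13 higher and 8 lower, and 0 passed with an estimated correlation (3 at an unadjusted p under 0.05), where their adjusted p ran from 0.627 to 0.767, while fry called all 21 in the same direction. As fry does not set a list against the other genes, these calls do not show that the lists moved more than those. Adjusted over the list alone, counts of calls equalled those over all genes except where given, and for complement and coagulation 8 rose in place of 7. Total count only moved the median of all genes by 0.48, called 6860 genes higher and 1057 lower (7917), ended the calls of collagens and matrix proteases (adjusted p = 0.10 and 0.0537) and ended those of 15 of the 92 named genes that kept their direction (Acta2, Alas2, Atp5a1, Atp5b, Cd36, Cdh19, Cxcl14, Folr2, G0s2, Gas6, H2-Aa, H2-Eb1, Ighm, Postn and Wt1), beside the 6 whose direction turned (Tpm1, Fabp4, Cd163, Zbtb46, Tapbp and H2-Q4), which were not called either. Named calls also ended with DESeq2 for Per1, Sox17 and Tap1, with limma-voom for Ighm, with the GC and length offset for Col15a1, Sox17 and Tap1, with no filter on low counts for H2-Aa, H2-Eb1, Ighm, Mki67, Per1, Postn, Tapbp and Tpm1 and in the fit of both groups alone for Mki67, Sox17 and Tpm1. They ended with each of at least 5 libraries left out in turn for Ighm, Per1, Postn, Sox17, Tap1 and Tpm1, and with 1 to 4 of the libraries for Ccnd1, Cd163, Cdh19, Col15a1, Gas6, H2-Aa, H2-Eb1, H2-Q4, Itgae, Krt18, Mrc1, Pf4, Tapbp and Zbtb46. Without mouse 6, a fit looked at after the data were seen, 8511 genes were called (4638 higher, 3873 lower).

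At 14 days after I/R, genes of fibroblasts, scar matrix and macrophages were higher than in sham. Comp (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066) of GRCm38, a matrix protein of cartilage and tendon, had 0.533 ± 0.101 CPM in sham and 40.5 ± 23.1 CPM at 14 days (SD, n = 3 per group, log2 fold 6.23, SE 0.49, edgeR adjusted p = 0.00121). Col8a2 (ENSMUSG00000056174, chromosome 4, 126286793 to 126314330), a collagen VIII chain, had 0.258 ± 0.0589 CPM in sham and 15.5 ± 6.29 CPM at 14 days (SD, n = 3 per group, log2 fold 5.94, SE 0.40, edgeR adjusted p = 2.21e-04). Jund (ENSMUSG00000071076, chromosome 8, 70698949 to 70700616), a subunit of the AP-1 transcription factor, had 14.2 ± 0.574 CPM in sham and 4.51 ± 0.851 CPM at 14 days (SD, n = 3 per group, log2 fold -1.67, SE 0.25, edgeR adjusted p = 0.00452), and its exons overlap an antisense gene. In all, 1236 genes rose and 797 fell, 2033 of 14124, and 39 passed a test against a 2-fold change. Library A stood nearer to sham than B and C: the Pearson correlation of log2 CPM with sham mouse 1 was 0.982 for A, 0.968 for B and 0.956 for C, and that of A was 0.987 with B and 0.978 with C (across genes, which are not independent replicates).

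Among called genes with at least 10 CPM in the higher group and groups that did not overlap, predicted, clone and unnamed genes left out, the other largest rises (log2 fold, SE) were in the secreted proteins Sfrp2 (5.05, SE 0.49), Ltbp2 (5.0, SE 0.52), Fmod (4.54, SE 0.66) and Angptl7 (4.48, SE 0.42). The other largest falls among such genes were in the cardiac transcription factor Nkx2-5 (-1.30, SE 0.19), G0s2 (-1.20, SE 0.17), Prob1 (-1.15, SE 0.14), Nr2f6 (-1.10, SE 0.18) and Endog (-1.08, SE 0.16). Genes called lower had a median GC content of 56.5%, against 49.5% over all tested genes. With the GC and length offset the calls of 11 of the 70 named genes ended, among them Bag3, Clec9a, Eng, Kcnq1, Nkx2-5, Notch3, Nr2f6, Pfkl, Smtn and Uqcrc1.

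Fibroblast and matrix genes rose. Of 12 late-scar fibroblast genes 10 rose (12 rose adjusted over the list alone, median log2 fold 4.07, camera adjusted p = 9.58e-12, adjusted p = 0.437 with an estimated correlation). The median of this list above the sham mean was 3.12, 3.67 and 4.73 in libraries A, B and C. Of 14 activated fibroblast and myofibroblast genes 11 rose and 1 fell (12 rose and 1 fell adjusted over the list alone, median log2 fold 2.7, camera adjusted p = 1.08e-08, adjusted p = 0.437 with an estimated correlation). Postn (3.49, SE 0.54) and Col8a1 (2.66, SE 0.27) were higher and Acta2 (-0.56, SE 0.15) was lower. Of 14 resting fibroblast genes 9 rose (10 rose adjusted over the list alone, median log2 fold 0.74, camera adjusted p = 3.73e-06, adjusted p = 0.437 with an estimated correlation). Dcn (1.48, SE 0.26) and Lamc1 (0.58, SE 0.14) were the most abundant called members. Of 19 collagen genes 15 rose (16 rose adjusted over the list alone, median log2 fold 1.67, camera adjusted p = 2.41e-10, adjusted p = 0.437 with an estimated correlation). The fibrillar chains Col3a1 (2.66, SE 0.42) and Col1a2 (2.12, SE 0.40) were the most abundant called members. Of 30 matrix glycoprotein and crosslinking genes 25 rose (26 rose and 1 fell adjusted over the list alone, median log2 fold 1.81, camera adjusted p = 7.44e-13, adjusted p = 0.437 with an estimated correlation). Sparc (1.71, SE 0.21) and Fbn1 (1.52, SE 0.25) were the most abundant called members. Of 19 matrix protease and inhibitor genes 12 rose (13 rose adjusted over the list alone, median log2 fold 1.32, camera adjusted p = 2.15e-07, adjusted p = 0.437 with an estimated correlation). Of 19 TGF-beta and activin genes 11 rose and 1 fell (median log2 fold 0.82, camera adjusted p = 2.21e-04, adjusted p = 0.510 with an estimated correlation).

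Immune lists were higher, though cytokines, interferon-stimulated genes and MHC class II did not pass by fry. Of 18 general macrophage genes 14 rose (17 rose adjusted over the list alone, median log2 fold 1.01, camera adjusted p = 1.5e-09, adjusted p = 0.437 with an estimated correlation). Lyz2 (1.35, SE 0.20) and the receptor Csf1r (0.55, SE 0.13) were the most abundant called members. Of 12 monocyte and early recruited macrophage genes 5 rose (7 rose adjusted over the list alone, median log2 fold 1.38, camera adjusted p = 0.00474, adjusted p = 0.510 with an estimated correlation). Vcan (1.48, SE 0.31) and Thbs1 (1.97, SE 0.32) were the most abundant called members, and both are also in the matrix glycoprotein list. The list medians above the sham mean in libraries A, B and C were 0.44, 1.09 and 1.43 for general macrophages, 0.36, 1.41 and 1.71 for monocytes and 0.14, 0.87 and 1.22 for MHC class II. Of 16 complement and coagulation genes 9 rose (10 rose adjusted over the list alone, median log2 fold 0.85, camera adjusted p = 1.64e-05, adjusted p = 0.437 with an estimated correlation). Of 7 dendritic cell genes 4 rose (6 rose and 1 fell adjusted over the list alone, median log2 fold 1.63, camera adjusted p = 0.00574, adjusted p = 0.437 with an estimated correlation), with Itgae (2.17, SE 0.54), Cd209a (2.56, SE 0.61), Flt3 (3.29, SE 0.72) and Clec9a (1.63, SE 0.48) higher. Of 23 cytokine and chemokine genes 5 rose (8 rose adjusted over the list alone, median log2 fold 0.51, camera adjusted p = 0.0455, adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.169). Cxcl16 (0.88, SE 0.24) and Cx3cl1 (0.90, SE 0.22) were the most abundant called members. Of 20 interferon-stimulated genes 2 rose (4 rose adjusted over the list alone, median log2 fold 0.37, camera adjusted p = 7.01e-04, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.0809), with Ifit2 (0.62, SE 0.11) and Ifit3 (1.19, SE 0.26) higher. Of 7 MHC class II genes 1 rose (5 rose adjusted over the list alone, median log2 fold 0.76, camera adjusted p = 0.00572, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.110), with H2-DMa (0.90, SE 0.22) higher. Of 3 mast cell genes 1 rose (median log2 fold 0.77, camera adjusted p = 0.0372, adjusted p = 0.437 with an estimated correlation), with Cpa3 (1.69, SE 0.36) higher.

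Of further higher lists, those of ribosomal proteins and the cell cycle did not pass by fry. Of 4 atrial cardiomyocyte genes 3 rose (median log2 fold 2.14, camera adjusted p = 4.47e-04, adjusted p = 0.437 with an estimated correlation), with Pam (0.70, SE 0.17), Dkk3 (3.85, SE 0.42) and Nppa (3.58, SE 0.35) higher. Only 4 of the 8 listed genes were tested, and Nppa is also in the cardiac stress list. These rises therefore do not show atrial cells in the tissue. Of 7 lymphatic endothelial genes 4 rose (5 rose adjusted over the list alone, median log2 fold 0.86, camera adjusted p = 0.00574, adjusted p = 0.446 with an estimated correlation), with Pdpn (1.40, SE 0.27), Reln (0.86, SE 0.23), Mmrn1 (1.58, SE 0.34) and Ccl21a (2.24, SE 0.43) higher and list medians of 0.23, 1.13 and 1.07 in libraries A, B and C. Of 32 cytosolic ribosomal protein genes 11 rose and 1 fell (13 rose and 1 fell adjusted over the list alone, median log2 fold 0.29, camera adjusted p = 1.27e-04, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.0505), and 2 rose with total count only. For the cell cycle, of 28 genes 0 were called (median log2 fold 0.41, camera adjusted p = 0.0372, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.376). Of these 3 had an unadjusted edgeR p under 0.05, and DESeq2 called 0 and limma-voom 0. The cardiac stress list did not pass: of 15 genes 6 rose (7 rose and 2 fell adjusted over the list alone, median log2 fold 0.61, camera adjusted p = 0.0533). Ankrd1 (1.36, SE 0.21) and Nppa were the most abundant called members. Nor did the neutrophil list, in which of 14 genes 1 fell (median log2 fold 0.02, camera adjusted p = 0.959), namely G0s2.

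Energy, contraction and red blood cell lists had small negative medians, and none of the 7 passed by fry. Of 50 nuclear-encoded oxidative phosphorylation genes 7 fell (9 fell adjusted over the list alone, median log2 fold -0.31, camera adjusted p = 1.44e-09, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.138). Uqcrc1 (-0.63, SE 0.19) and Cox5a (-0.47, SE 0.13) were the most abundant called members. Of 28 fatty acid genes 1 fell (0 were called adjusted over the list alone, median log2 fold -0.44, camera adjusted p = 7.64e-06, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.177), namely Acot2 (-0.69, SE 0.18), while 11 had an unadjusted edgeR p under 0.05, and DESeq2 called 4 and limma-voom 1. Of 15 tricarboxylic acid cycle genes 0 were called (median log2 fold -0.34, camera adjusted p = 1.87e-04, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.159). In the cycle 8 had an unadjusted edgeR p under 0.05, and DESeq2 called 2 and limma-voom 0. Of 7 mitochondrially encoded messenger RNAs 0 were called (median log2 fold -0.48, camera adjusted p = 0.00987, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.177). Of these messengers 1 had an unadjusted edgeR p under 0.05, and DESeq2 called 1 and limma-voom 0. Of 20 calcium handling and ion channel genes 3 fell (median log2 fold -0.37, camera adjusted p = 5.04e-04, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.177). Jph2 (-0.84, SE 0.16) and Kcnq1 (-0.56, SE 0.16) were the most abundant called members. Of 20 sarcomere genes 1 fell (0 were called adjusted over the list alone, median log2 fold -0.23, camera adjusted p = 0.00345, adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.267), while 3 had an unadjusted edgeR p under 0.05, and DESeq2 called 3 and limma-voom 1. Of 5 red blood cell genes 1 fell (2 fell adjusted over the list alone, median log2 fold -0.43, camera adjusted p = 0.0396, adjusted p = 0.510 with an estimated correlation, fry adjusted p = 0.195), with Hba-a2 (-0.88, SE 0.20) lower. The blood endothelial list did not pass: of 18 genes 1 fell (median log2 fold -0.01, camera adjusted p = 0.369), namely Eng (-0.38, SE 0.09). That median was 0.08 with total count only, where 3 oxidative phosphorylation genes fell.

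For the remaining 13 tested lists camera adjusted p was 0.0611 or more. Their called members, where these were 5 or fewer, were Pdgfrb (0.49, SE 0.10) and Tagln (0.78, SE 0.21) higher and Smtn (-0.66, SE 0.12), Acta2 (-0.56, SE 0.15) and Notch3 (-0.47, SE 0.12) lower for smooth muscle and pericytes and Hsph1 (-0.50, SE 0.12) and Bag3 (-0.42, SE 0.10) lower for heat shock. They were Mrc1 (0.82, SE 0.17) and Gas6 (0.61, SE 0.16) higher for resident macrophages, Ighm (1.32, SE 0.33) higher for B cells and Mbp (0.95, SE 0.28) and Cdh19 (0.90, SE 0.18) higher for Schwann cells. They were Tbx18 (0.87, SE 0.16) higher and Wt1 (-0.88, SE 0.21) lower for epicardium, Pfkfb3 (0.77, SE 0.17) higher and Pfkl (-0.50, SE 0.14) lower for glycolysis and Ndrg1 (0.44, SE 0.10) higher and Higd1a (-0.43, SE 0.11) lower for hypoxia. For the NRF2 list they were Slc7a11 and Mt2 (1.34, SE 0.28) higher. Slc7a11 had 19 counts over the 14-day libraries and 3 over the sham libraries, a ratio of 5.01 with a 95% counting interval of 1.48 to 26.4.

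Of the 42 lists 26 passed, 19 higher and 7 lower, and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), where their adjusted p ran from 0.437 to 0.682, while fry called 14 of the 19 higher lists in the same direction. Adjusted over the list alone, counts equalled those over all genes except where given and for glycolysis (1 rose, 2 fell), hypoxia (1 rose, 3 fell), immediate early genes (4 rose, 4 fell) and MHC class I (3 rose). The number of called genes was 912, 478 and 1025 without sham mouse 1, 2 or 3, 3012, 722 and 775 without library A, B or C, 3221 without mouse 6 and 832 (720 higher, 112 lower) with total count only, which ended the calls of 24 of the 70 named genes, among them Acot2, Acta2, Bag3, Col1a2, Cox5a, Csf1r, Eng, Hba-a2, Higd1a, Hsph1, Kcnq1, Lamc1, Mbp, Ndrg1, Notch3, Pdgfrb, Pfkl, Reln, Slc7a11, Tagln, Uqcrc1, Vcan and Wt1. Named calls also ended with DESeq2 for Clec9a and Slc7a11, with limma-voom for Cd209a, Clec9a, Cxcl16, Ighm, Mbp, Reln and Tagln, with no filter on low counts for Acot2, Cxcl16, Ighm, Mmrn1, Reln and Vcan and in the fit of both groups alone for Cxcl16, Ighm and Mmrn1. They ended with each of at least 5 libraries left out in turn for Acot2, Bag3, Cd209a, Clec9a, Cox5a, Csf1r, Cxcl16, Gas6, Higd1a, Ighm, Itgae, Kcnq1, Lamc1, Mbp, Pam, Pfkl, Reln, Slc7a11 and Uqcrc1, and with 1 to 4 of the libraries for Acta2, Ccl21a, Cdh19, Col1a2, Cpa3, Cx3cl1, Eng, Flt3, H2-DMa, Hba-a2, Hsph1, Ifit3, Mmrn1, Mrc1, Mt2, Ndrg1, Notch3, Pdpn, Pfkfb3, Tagln, Vcan and Wt1. List calls ended for the cell cycle (without sham mouse 1, sham mouse 3 or library B, with total count only or with the GC and length offset), cytokines (without mouse 5 or library B, or with the offset), mast cells (without library B) and red blood cells (without sham mouse 2 or 3).

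**Figure D2:**
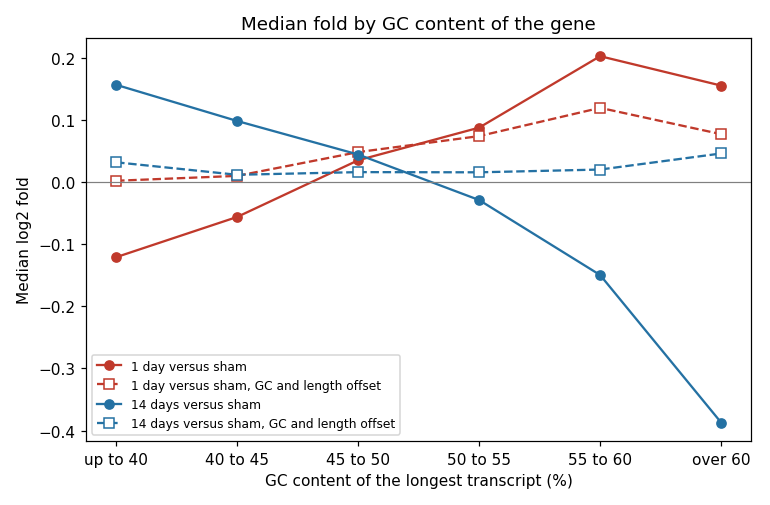
Lines give the median log2 fold against sham of genes in bins of GC content (percent of the longest transcript), at 1 day and 14 days, with and without the offset for GC content and length. At 14 days the bin above 60% had a median of -0.39 without the offset and 0.05 with it.

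**Figure D3:**
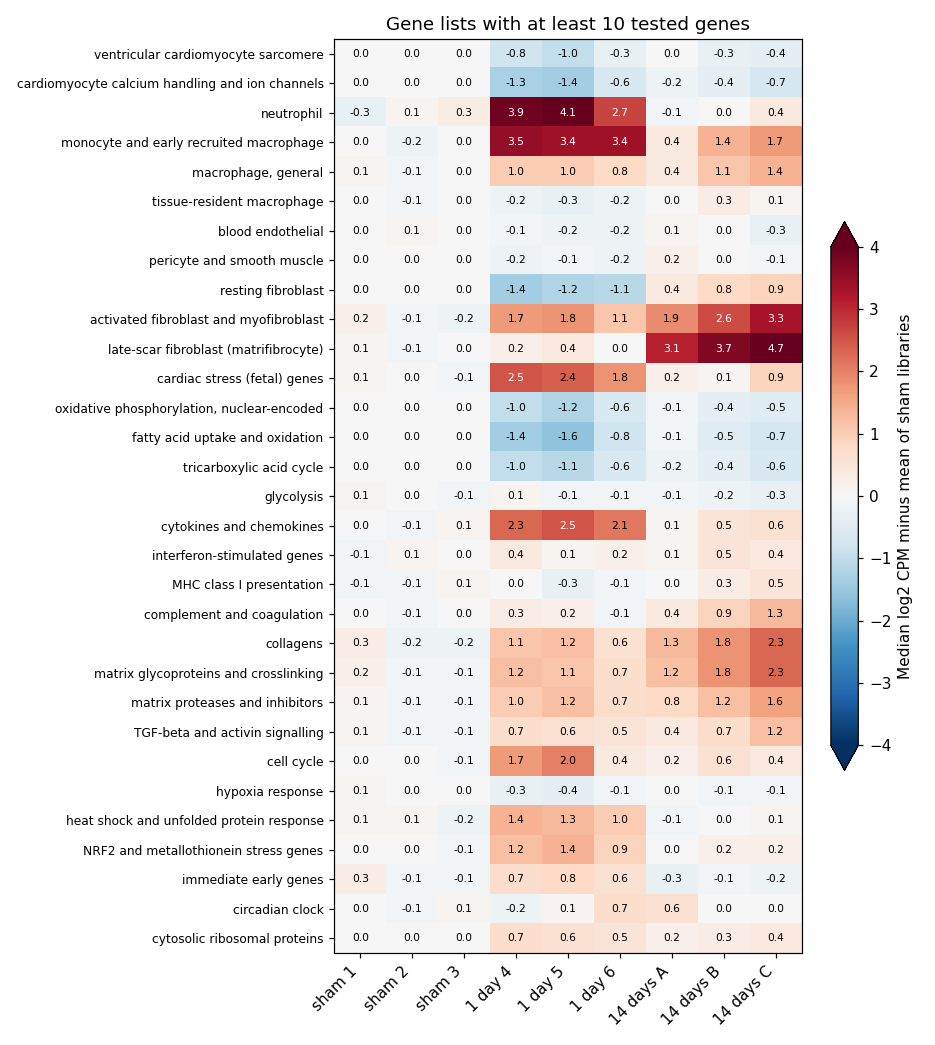
Colour gives the median, over the tested genes of a list, of log2 CPM minus the sham mean, per library, for lists with at least 10 tested genes (scale capped at -4 and 4). The neutrophil list has its highest values in the 1-day libraries (2.71 to 4.10) and the late-scar fibroblast list in the 14-day libraries (3.12 to 4.73).

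**Figure D4:**
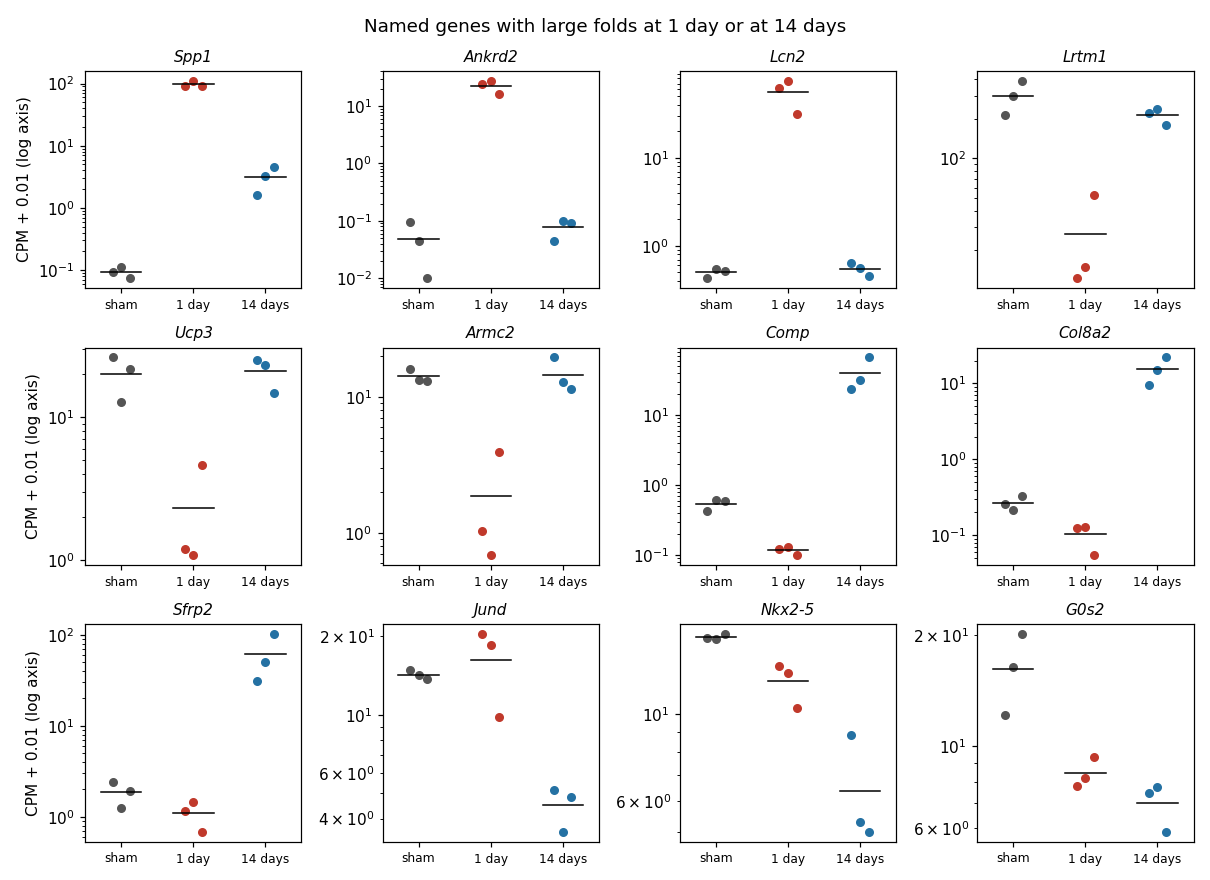
Points give CPM plus 0.01 per library on a log axis for 12 genes with at least 10 CPM in the higher group, by group (3 libraries each), and bars the group mean. Spp1, Ankrd2 and Lcn2 were highest at 1 day, and Comp, Col8a2 and Sfrp2 at 14 days.

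From 1 day to 14 days, neutrophil, monocyte, cytokine, stress and cell cycle genes fell. Genes of resting and late-scar fibroblasts rose, as did, with TMM scaling, genes of energy metabolism. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) of GRCm38, which encodes arginase, had 1755 counts over the 1-day libraries and 3 over the 14-day libraries, a ratio of 558 with a 95% counting interval of 191 to 2708. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) had 10.2 ± 1.75 CPM at 1 day and 0.0486 ± 0.0289 CPM at 14 days (SD, n = 3 per group, log2 fold -7.68, SE 0.29, edgeR adjusted p = 1.16e-07). Comp had 0.107 ± 0.0156 CPM at 1 day and 40.5 ± 23.1 CPM at 14 days (SD, n = 3 per group, log2 fold 8.47, SE 0.59, edgeR adjusted p = 1.97e-05). In all, 3547 genes rose and 3788 fell, 7335 of 14124, and 626 passed a test against a 2-fold change.

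Among called genes with at least 10 CPM in the higher group and groups that did not overlap, predicted, clone and unnamed genes left out, the other largest rises (log2 fold, SE) were in Col8a2 (7.24, SE 0.43), Fmod (5.85, SE 0.73), Sfrp2 (5.77, SE 0.51) and Dkk3 (5.09, SE 0.46). Angptl7 had 885 counts over the 14-day libraries and 1 over the 1-day libraries, a ratio of 928 with a 95% counting interval of 166 to 36689. The other largest falls among such genes were in Ankrd2 (-8.27, SE 0.34), Lcn2 (-6.67, SE 0.37), the matrix protease Mmp9 (-5.20, SE 0.71) and Slfn4 (-5.19, SE 0.29). Genes called lower had a median GC content of 52.6% and genes called higher 46.9%, against 49.5% over all tested genes. In the bin above 60% GC the median log2 fold was -0.55, and -0.03 with the GC and length offset. With that offset 6980 genes were called, 6015 of the 7335 in the same direction and 3 in the opposite, namely Ube2m (-0.23 to 0.29), Fkbp8 (-0.27 to 0.28) and Gm22973 (0.30 to -0.35), which are named because of these values.

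Neutrophil, monocyte, cytokine, stress and growth lists fell. Of 14 neutrophil genes 12 fell (median log2 fold -4.32, camera adjusted p = 1.30e-06, adjusted p = 0.589 with an estimated correlation). Lcn2 and Csf3r (-4.08, SE 0.46) were the most abundant called members. Of 12 monocyte and early recruited macrophage genes 9 fell (10 fell adjusted over the list alone, median log2 fold -1.86, camera adjusted p = 3.09e-05, adjusted p = 0.589 with an estimated correlation). Spp1 (-4.96, SE 0.27) and Ccr2 (-1.5, SE 0.30) were the most abundant called members. Of 23 cytokine and chemokine genes 17 fell and 2 rose (18 fell and 3 rose adjusted over the list alone, median log2 fold -1.89, camera adjusted p = 2.94e-05, adjusted p = 0.589 with an estimated correlation). Csf1 (-0.96, SE 0.11) and Ccl6 (-1.89, SE 0.16) were lower and Cxcl14 (0.93, SE 0.20) was higher. Of 15 cardiac stress genes 12 fell (median log2 fold -1.79, camera adjusted p = 2.86e-07, adjusted p = 0.589 with an estimated correlation). Xirp2 (-2.48, SE 0.23) and Flnc (-3.87, SE 0.27) were the most abundant called members. Of 18 heat shock and unfolded protein response genes 14 fell (median log2 fold -1.13, camera adjusted p = 1.06e-05, adjusted p = 0.589 with an estimated correlation). Of 12 NRF2 target and metallothionein genes 9 fell and 2 rose (median log2 fold -1.33, camera adjusted p = 0.00142, adjusted p = 0.589 with an estimated correlation). Of 18 immediate early genes 10 fell and 2 rose (11 fell and 2 rose adjusted over the list alone, median log2 fold -0.78, camera adjusted p = 0.0238, adjusted p = 0.692 with an estimated correlation). Of 28 cell cycle genes 24 fell (24 fell and 1 rose adjusted over the list alone, median log2 fold -1.25, camera adjusted p = 1.34e-04, adjusted p = 0.692 with an estimated correlation). Ccnd1 (-0.36, SE 0.11) and Mki67 (-1.15, SE 0.39) were the most abundant called members. Of 32 cytosolic ribosomal protein genes 19 fell (median log2 fold -0.34, camera adjusted p = 1.01e-04, adjusted p = 0.692 with an estimated correlation), and 27 fell with total count only (median -0.72).

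Resting and late-scar fibroblast, energy and contraction lists were higher, though both contraction lists and MHC class II did not pass by fry. Of 14 resting fibroblast genes 12 rose (median log2 fold 1.96, camera adjusted p = 1.18e-06, adjusted p = 0.589 with an estimated correlation). Gsn (2.16, SE 0.24) and Dcn (2.65, SE 0.27) were the most abundant called members. Of 12 late-scar fibroblast genes 9 rose and 2 fell (median log2 fold 3.41, camera adjusted p = 0.00146, adjusted p = 0.692 with an estimated correlation). Of 50 nuclear-encoded oxidative phosphorylation genes 40 rose (41 rose adjusted over the list alone, median log2 fold 0.61, camera adjusted p = 4.32e-08, adjusted p = 0.692 with an estimated correlation). Atp5a1 (0.56, SE 0.20) and Atp5c1 (0.72, SE 0.18) were the most abundant called members. Of 28 fatty acid genes 25 rose (median log2 fold 0.75, camera adjusted p = 1.18e-06, adjusted p = 0.692 with an estimated correlation). Lpl (0.85, SE 0.27) and Cd36 (0.71, SE 0.17) were the most abundant called members. Of 15 tricarboxylic acid cycle genes 13 rose (median log2 fold 0.55, camera adjusted p = 6.82e-04, adjusted p = 0.692 with an estimated correlation). Of 20 sarcomere genes 8 rose and 1 fell (median log2 fold 0.39, camera adjusted p = 0.0233, adjusted p = 0.744 with an estimated correlation, fry adjusted p = 0.0988). Myh6 (0.92, SE 0.32) and Myl2 (1.18, SE 0.22) were higher and Smpx (-0.42, SE 0.10) was lower. Of 20 calcium handling and ion channel genes 11 rose and 2 fell (11 rose and 3 fell adjusted over the list alone, median log2 fold 0.75, camera adjusted p = 0.0239, adjusted p = 0.744 with an estimated correlation, fry adjusted p = 0.101). Atp2a2 (0.88, SE 0.31) and Pln (1.63, SE 0.35) were higher. Total count only left 4 oxidative phosphorylation genes higher (median log2 fold 0.23), 10 fatty acid genes (0.38) and 1 tricarboxylic acid cycle gene (0.17). Of the sarcomere 4 rose and 3 fell there (median 0.02), and of calcium handling 7 rose and 3 fell (median 0.39). Of 7 MHC class II genes 5 rose (median log2 fold 1.21, camera adjusted p = 0.0404, adjusted p = 0.692 with an estimated correlation, fry adjusted p = 0.0809), with Cd74 (1.21, SE 0.25), H2-Aa (1.88, SE 0.29), H2-DMa (0.53, SE 0.21), H2-Eb1 (1.63, SE 0.28) and H2-Ab1 (1.46, SE 0.27) higher.

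Some lists did not pass and went both ways. Of 19 collagen genes 9 rose and 4 fell (10 rose and 4 fell adjusted over the list alone, median log2 fold 0.82, camera adjusted p = 0.0552). Col3a1 (1.91, SE 0.41) and Col1a2 (1.32, SE 0.39) were higher and Col4a1 (-1.04, SE 0.17) was lower. Of 30 matrix glycoprotein and crosslinking genes 12 rose and 6 fell (median log2 fold 0.40, camera adjusted p = 0.157). Sparc (0.94, SE 0.21) and Postn (2.11, SE 0.50) were higher and the collagen chaperone Serpinh1 (-1.22, SE 0.22) was lower. Of 14 activated fibroblast genes 9 rose and 2 fell (median log2 fold 1.06, camera adjusted p = 0.0512). Postn and Col8a1 (0.93, SE 0.25) were higher and Tnc (-2.79, SE 0.53) was lower. Of 18 general macrophage genes 6 rose and 4 fell (7 rose and 4 fell adjusted over the list alone, median log2 fold 0.15, camera adjusted p = 0.804), with Csf1r (0.43, SE 0.13) and the complement gene C1qa (0.74, SE 0.20) higher and Laptm5 (-0.73, SE 0.18) lower. Of 18 blood endothelial genes 6 rose and 2 fell (median log2 fold 0.20, camera adjusted p = 0.179), with Fabp4 (0.54, SE 0.13) and Kdr (1.02, SE 0.15) higher and Eng (-0.51, SE 0.09) lower. With total count only 5 rose and 4 fell among collagens, 8 fell and 6 rose among matrix glycoproteins, 4 rose and 2 fell among activated fibroblast genes, 4 fell among general macrophage genes (median turned to -0.23) and 4 fell and 1 rose among blood endothelial genes (median turned to -0.21). With the GC and length offset 10 rose and 1 fell among blood endothelial genes (median 0.31). For the remaining 20 tested lists camera adjusted p was 0.0625 or more.

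Called members of those lists with 5 or fewer calls were Prox1 (1.07, SE 0.17), Reln (1.07, SE 0.23), Mmrn1 (2.03, SE 0.35) and Ccl21a (2.97, SE 0.44) higher and Pdpn (-1.75, SE 0.22) lower for lymphatic endothelium. They were Tbx18 (0.52, SE 0.15) higher and Aldh1a2 (-2.95, SE 0.24) and Krt18 (-1.47, SE 0.45) lower for epicardium, Cdh19 (1.5, SE 0.19) and Kcna1 (1.77, SE 0.27) higher and Mbp (-0.68, SE 0.24) lower for Schwann cells and Gas6 (1.11, SE 0.17) and Folr2 (0.94, SE 0.15) higher and F13a1 (-0.40, SE 0.15) lower for resident macrophages. They were Hbb-bs (0.99, SE 0.20) and Hbb-bt (1.13, SE 0.21) higher for red blood cells, Pam (1.04, SE 0.17) and Dkk3 (5.09, SE 0.46) higher for the atrium and Npas2 (1.41, SE 0.24) and Arntl (1.23, SE 0.30) higher and Bhlhe41 (-1.05, SE 0.11) and Per2 (-1.47, SE 0.30) lower for the clock. Single calls in a list were Ighm (2.49, SE 0.35) higher for B cells, Clec10a (0.87, SE 0.25) higher for dendritic cells, Cpa3 (1.74, SE 0.34) higher for mast cells, Ppbp (-1.35, SE 0.42) lower for platelets and Cd28 (1.25, SE 0.18) higher for T cells. For fast skeletal muscle they were Myl1 (0.64, SE 0.20) higher and Tnnt3 (-2.50, SE 0.56) lower.

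Of the 42 lists 17 passed, 8 higher and 9 lower, and 0 passed with an estimated correlation (1 at an unadjusted p under 0.05), where their adjusted p ran from 0.589 to 0.744, while fry called 14 of them in the same direction. Adjusted over the list alone, counts equalled those over all genes except where given and for resident macrophages (2 rose), T cells (2 rose), Schwann cells (3 rose and 1 fell), red blood cells (4 rose), complement and coagulation (9 rose and 6 fell), TGF-beta (9 fell and 7 rose) and hypoxia (9 rose and 3 fell). Total count only moved the median of all genes by -0.39, called 1066 genes higher and 5469 lower, and ended the immediate early gene call (adjusted p = 0.0509) and those of 21 of the 81 named genes (Arntl, Atp2a2, Atp5a1, Atp5c1, C1qa, Cd36, Clec10a, Col1a2, Col8a1, Csf1r, Cxcl14, Fabp4, Folr2, H2-DMa, Lpl, Myh6, Myl1, Postn, Reln, Sparc and Tbx18). Named calls also ended with DESeq2 for H2-DMa, with limma-voom for H2-DMa and Mki67, with the GC and length offset for Eng, Laptm5 and Myl1, with upper-quartile scaling for F13a1, with no filter on low counts for Col1a2, Col8a1, H2-DMa, Mki67 and Ppbp and in the fit of both groups alone for Atp2a2, Atp5a1, F13a1, H2-DMa, Lpl, Mbp and Myh6. They ended with each of at least 5 libraries left out in turn for Atp2a2, Atp5a1, F13a1 and H2-DMa, and with 1 to 4 of the libraries for C1qa, Ccnd1, Clec10a, Col1a2, Col8a1, Csf1r, Krt18, Lpl, Mbp, Mki67, Myh6, Myl1, Postn, Ppbp and Tbx18. List calls ended for the sarcomere (without mouse 5 or library A), calcium handling (without mouse 4, mouse 5 or library A) and MHC class II (without any 1 library other than A).

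Of genes called at 1 day against sham and in the opposite direction from 1 day to 14 days, but not at 14 days against sham, 2722 were higher and 2314 lower at 1 day. At both times 621 genes were higher and 376 lower than sham. At 14 days against both other groups, with no call at 1 day, 416 were higher and 259 lower. Another 98 rose at 1 day and fell at 14 days against sham, and 106 did the opposite. These counts moved widely with 1 library left out, as given below for each pattern. Both comparisons used the same sham libraries. Their log2 folds had a Pearson correlation of 0.394 and a Spearman correlation of 0.410 across genes, which are not independent replicates, and 63.8% had the same sign. Simulated unchanged groups against shared controls (20 simulations) gave 0.527, 0.491 and 67.6%. The covariance was 0.212 against 0.0295 simulated, a difference of 0.182. Independent lists of these sizes would share 363 higher and 197 lower genes. Sham could not be split into parts of 2 libraries, so part of the excess may come from the shared controls.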

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

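The tests of explanations below, and what the splits of the samples would show, were chosen or written after the results they bear on were seen, while 14 days against 1 day, which tests the difference of both effects, was fixed before.

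Some genes and 1 list moved one way at 1 day and the other way at 14 days, each against the same sham libraries. There were 98 genes higher at 1 day and lower at 14 days, and 106 lower at 1 day and higher at 14 days, against 17 and 30 with total count only, and from 15 to 224 and from 35 to 176 with 1 library left out. More genes moved the same way at both times, 621 higher and 376 lower. The number that independent lists would share in opposite directions was not computed, so these counts show no excess. Among the named genes, the log2 folds against sham at 1 day and at 14 days, in that order, and their difference (edgeR, each with adjusted p under 0.05) were those of the matrix genes Dcn (-1.17 and 1.48, difference 2.65, SE 0.27) and Fbln1 (-1.56 and 2.04, difference 3.60, SE 0.32), the Schwann cell gene Cdh19 (-0.61 and 0.90, difference 1.5, SE 0.19), Gas6 (-0.50 and 0.61, difference 1.11, SE 0.17), the immunoglobulin gene Ighm (-1.18 and 1.32, difference 2.49, SE 0.35) and the chaperone Hsph1 (0.34 and -0.50, difference -0.84, SE 0.12). Against sham at 1 day the calls of Cdh19, Gas6 and Ighm ended with total count only, and at 14 days that of Hsph1. Those of Ighm ended with limma-voom and with no filter on low counts at both times, and at 14 days in the fit of both groups alone. The 1-day calls ended without sham mouse 2, sham mouse 3, mouse 4 or mouse 5 for Cdh19, without sham mouse 1, sham mouse 2, mouse 4 or mouse 5 for Gas6 and without sham mouse 1, sham mouse 2, mouse 4, mouse 5 or mouse 6 for Ighm. The 14-day calls ended without sham mouse 2 for Cdh19, sham mouse 1, sham mouse 2, sham mouse 3, library B or library C for Gas6, sham mouse 1, sham mouse 2, sham mouse 3, mouse 6, library B or library C for Ighm and sham mouse 2, library B or library C for Hsph1. Angptl7 had a fitted difference of 9.39, but with 1 count over the 1-day libraries that size depends on the fit and the counting interval of its ratio runs from 166 to 36689. The resting fibroblast list fell at 1 day and rose at 14 days against sham, with a median log2 fold of 1.96 between both times, though with an estimated correlation the adjusted p was 0.659 at 1 day, 0.437 at 14 days and 0.589 between both times.

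The 1-day library of mouse 6 lay between sham and mice 4 and 5, with a median of 59.8% of their change. The median covers 2898 genes that changed over 2-fold in the mean of mice 4 and 5. A mix of injured and uninjured tissue in 1 proportion would give about that share in every list. Of 20 lists with at least 8 genes, 9 differed from it by more than 2 bootstrap SE, against 3 of 20 for mouse 5 measured on mouse 4. But genes higher in mice 4 and 5 showed a median of 53.1% and genes lower 65.8%, so part of a list's distance may follow its direction. The oxidative phosphorylation (64.0%) and fatty acid (65.9%) lists, among the 9, lay near the value of the lower genes, while the cell cycle list (15.7%) lay far from both. Mouse 5 also helped to pick the genes, so the count cannot decide on such a mix. This count replaced a first test on the highest and lowest list, and the bootstrap treats genes as independent. Mouse 5 had 9.27M counts without ribosomal RNA against 9.32M in mouse 6 and showed a median of 99.6% of the change of mouse 4. As mouse 5 helped to pick the genes and mouse 6 did not, these shares cannot decide on lower depth. Of the sham and 14-day libraries 0 correlated best with a 1-day library, which argues against a swap within the series. A mix of tissue, lower depth, a milder or differently timed injury, other sampling of the tissue and a swap with a mouse outside the series stay open. Of these, the injury, the sampling and a swap with an outside mouse were not tested.

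Genes called lower at 14 days were rich in GC, and the slope of log2 CPM per 10% GC was -0.11, -0.19 and -0.18 in the 14-day libraries against 0.07, 0.04 and -0.04 in sham and 0.24, 0.08 and 0.09 at 1 day, a mean difference of -0.18 from sham and -0.29 from 1 day (two-sided exact permutation p = 0.1 for each, the smallest possible with n = 3 per group). With an offset for GC content and length 389 of the 797 lower calls were called lower again (median log2 fold -0.60 before and -0.51 after). This argues against the part of that trend that the offset removes as their whole cause. The 389 had a median GC content of 53.4%, against 49.5% over all tested genes, so a trend that the offset left in place is not excluded. For the other 408 the median moved from -0.53 (median SE 0.13) to -0.30 (median SE 0.12), and their calls ended because the fold shrank at about the same SE. The first bound set for them, a median below 0 by more than 2 median SE, was met, but it was withdrawn after the value was seen, because genes picked for being lower keep a remainder by selection. For these 408 a GC or length trend and a change in the tissue cannot be told apart.

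Energy metabolism genes fell at 1 day in 92 of 93 members. With total count only 59 of 93 were still called lower (median -0.96 before and -0.50 after), which argues against scaling as the whole cause. For the sarcomere 8 of 20 were called lower with total count only, against 13 (median -0.54 before and -0.07 after), which leaves scaling open. The totals in that setting include mitochondrial ribosomal RNAs, on average 60.2% of counts in sham and 53.4% at 1 day. It shifted log2 folds at 1 day by a median of 0.48. DESeq2 size factors, upper-quartile scaling and scaling without mitochondrially encoded genes shifted them by -0.04, -0.02 and -0.01. A lower share of cardiomyocytes would move genes alike if only cardiomyocytes expressed them. Of 40 sarcomere and calcium-handling genes 20 differed from their median of -0.83 by more than 2 SE. Expression of members in other cells was not measured and would also spread the folds, so this count cannot decide on that share. A lower share, as a part or the whole cause, and a change within cardiomyocytes after I/R stay open.

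Of 100 drawn splits of the 9 libraries into 3 groups of 3, only the real 1 gave as many as 8897 genes, and the highest other gave 5686, so chance can be excluded. For each pair of groups 1 of 10 splits, the real one, gave as many genes (7649, 2033 and 7335, the highest other 0 by edgeR in each), and 10 splits are too few for a share under 0.05.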

How the results depend on the processing

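The GC and length offset was chosen after the data were seen, and the other alternatives before. Over the counts, shares and named genes under all alternatives 4445 values kept their direction and side of the threshold (or stayed within 1.5 times for counts), 603 kept the direction without passing, 57 moved by more than that and 10 turned. These values do not include medians of gene lists or genes outside the rule for named genes, some of which turned, as given above. A test against a 2-fold change called 810, 39 and 626 genes (1 day against sham, 14 days against sham, 14 days against 1 day), which its construction explains. For the rest the cause was not tested. Total count only gave 832 genes at 14 days against sham. Leaving out 1 library gave 6145 to 8511, 478 to 3221 and 5604 to 8360 genes. Lists called with an estimated correlation were 0, 0 and 0 (camera), and fry called 16 at 14 days against sham. Time patterns are given as the value, that with total count only and the range with 1 library left out. Higher at 1 day only had 2722, 4711 and 1947 to 2931 genes, and lower at 1 day only 2314, 609 and 1699 to 2561. Higher at both times had 621 and, left out, 118 to 993, and lower at both times 376, 34 and 63 to 830. Higher at 14 days only had 416, 184 and 153 to 531, and lower at 14 days only 259, 52 and 75 to 317. Higher then lower had 98, 17 and 15 to 224, and lower then higher 106, 30 and 35 to 176. At 14 days minus sham the mitochondrial share differed by -0.234 percentage points (-1.57 to 1.81 with 1 library left out, 1.81 without sham mouse 3 and 0.974 without library C) and that of the 10 most abundant genes by -0.807 (-1.99 to 0.932, with 0.932 and 0.394 without the same libraries). With total count only the log2 folds at 1 day turned for Tpm1 (0.00685), Fabp4 (0.00674), Cd163 (0.0184), Zbtb46 (0.119), Tapbp (0.230) and H2-Q4 (0.0770). Of 92, 70 and 81 named genes 60, 24 and 52 kept their call under every alternative in which they were tested, the test against a 2-fold change left out. Some named genes were not tested with the filter of 1 CPM in 3 libraries or in the fit of the groups compared alone. No paired analysis was possible because the groups share no replicate numbers. Depth limits low genes such as Ankrd2, Arg1, Angptl7 and Slc7a11, which had 1 to 3 counts in a group.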

Other observations

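The families in this part were picked after the data were examined: 39 were looked at, 36 had at least 3 tested genes, and 41 of their 108 camera tests passed, with 0 passing with an estimated correlation (1 at an unadjusted p under 0.05, lowest adjusted p 0.562).

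At 1 day the tubulin, chaperonin and proteasome families and genes named Nop, Nol, Utp or Wdr were higher than in sham. The potassium channel and mitochondrial ribosomal families were lower. Of 13 alpha and beta tubulin genes 9 rose and 2 fell (median log2 fold 1.83, 2.33 with total count only, camera adjusted p = 0.0207, adjusted p = 0.564 with an estimated correlation). Of 6 subunits of the chaperonin that folds tubulin and actin 6 rose (median log2 fold 0.86, 1.36 with total count only, camera adjusted p = 0.00267, adjusted p = 0.564 with an estimated correlation). Of 81 genes with symbols that begin with Nop, Nol, Utp or Wdr 44 rose and 5 fell (median log2 fold 0.40, 0.88 with total count only, camera adjusted p = 1.39e-04, adjusted p = 0.562 with an estimated correlation). Of 38 proteasome subunit genes 15 rose (median log2 fold 0.25, 0.74 with total count only, camera adjusted p = 0.00987, adjusted p = 0.576 with an estimated correlation). Of 43 potassium channel genes 22 fell and 7 rose (median log2 fold -0.60, -0.12 with total count only, camera adjusted p = 0.0144, adjusted p = 0.562 with an estimated correlation). Of 47 large-subunit mitochondrial ribosomal protein genes 35 fell and 1 rose (median log2 fold -0.48, 0.00 with total count only, camera adjusted p = 3.09e-08, adjusted p = 0.562 with an estimated correlation), and of 29 small-subunit genes 18 fell and 1 rose (median log2 fold -0.42, 0.06 with total count only, camera adjusted p = 1.39e-04, adjusted p = 0.562 with an estimated correlation), so that both medians turned with total count only.

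At 14 days small RNAs were higher than in sham. Of 59 small nucleolar RNA genes 13 rose (median log2 fold 0.49, 0.58 with total count only, 0.34 with the GC and length offset, camera adjusted p = 3.39e-05, adjusted p = 0.562 with an estimated correlation). At 1 day 14 of them rose and 5 fell against sham (median log2 fold 0.15, 0.48 with that offset, camera adjusted p = 0.511). From 1 day to 14 days their median of 0.35 turned to -0.14 with the offset. Of 16 small nuclear RNA genes 6 rose (median log2 fold 0.61, 0.70 with total count only, 0.45 with the GC and length offset, camera adjusted p = 2.38e-04, adjusted p = 0.562 with an estimated correlation). At 1 day 2 of these rose and 3 fell against sham (median log2 fold -0.29, 0.08 with the offset). From 1 day to 14 days of 34 histone genes of the Hist clusters 26 fell and 1 rose (median log2 fold -1.59, -2.01 with total count only, camera adjusted p = 6.05e-04, adjusted p = 0.656 with an estimated correlation).

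Of 15 clock genes 13 had a value in mouse 6 outside the range of the sham mice and mice 4 and 5, against 15.8% of all tested genes. The median of the clock list above the sham mean was 0.69 in mouse 6 and 0.60 in library A, against -0.23 and 0.07 in mice 4 and 5 and -0.03 and -0.02 in libraries B and C. In libraries A, B and C, in that order, Per1 had 18.6, 5.60 and 6.99 CPM and Dbp 14.3, 10.2 and 8.91 CPM. The labels used here give no hour of collection. Counts of mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 ran from 0 to 3 per library, while mt-Co1 had 472303 to 1017943. The gene ENSMUSG00000045999, which is not in the annotation used here, took from 0.0300% of the counts in library B to 1.43% in mouse 6.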
